A study of Neurospora crassa with 42 samples.

How the data were processed

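Total RNA of Neurospora crassa mycelia was extracted with TRIzol and made into libraries by the BGI protocol, per the labels, for 42 libraries in 14 groups of 3. The authors deposited 3 tables, 1 per experiment, each with 1 column per library of FPKM values (mapped fragments corrected for transcript length and library size) rounded to 2 decimals. Beside these, the deposited tables hold the authors' log2 fold changes between pairs of groups. They also hold the authors' adjusted p-values (q-values) of those comparisons, which the deposited headers assign to DESeq2. Other deposited columns give gene start, gene end and longest transcript length in bp. HISAT2 2.0.4 and Bowtie2 2.2.5 are named in the submitters' processing notes without their roles, and the genome build and the program that computed FPKM are not given in the sources used here. The gene models differed between the tables: transcript lengths were multiples of 3 for 43.5%, 42.1% and 87.8% of genes in the inhibitor, sah2 and atrR tables, so levels were not compared between experiments.

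The tables named 9763, 10596 and 10817 gene entries in the inhibitor, sah2 and atrR experiments. Entries without a value in any library (548, 1036 and 944) were left out, 1 entry without a gene name was dropped, and 1690 entries of loci listed more than once in the atrR table were summed per locus, which left 9215, 9560 and 8966 loci. Per library the FPKM summed to 585892 to 628169, 629684 to 702678 and 906085 to 1027435, the median over loci above 0 was 11.44 to 15.04, 6.46 to 12.23 and 12.94 to 20.56, and the 10 most abundant loci took 11.8% to 15.8%, 13.0% to 18.4% and 10.4% to 22.2%. Loci of at least 1 FPKM numbered 7051 to 7644, 7105 to 7738 and 7142 to 7718. The files give no counts. Depth was estimated from the steps between low FPKM values and transcript length, at 13.3 to 19.5 M fragments per library, with 90.0% to 100.0% of the values used lying within 0.15 of a whole number of fragments. Depth and effective length were chosen per library, within preset ranges, to bring these values nearest to whole numbers, so the share is no check. The estimates carry the error of the fitted effective lengths and were used only to compare libraries.

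FPKM values were scaled between the libraries of an experiment by an unweighted trimmed mean of log ratios (trim 0.3 of the ratios and 0.05 of the means), written for this purpose. Genes with at least 1 FPKM in at least 3 libraries of an experiment were kept, 7806, 7886 and 7758 in all. Log2(scaled FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group of an experiment and an intensity trend for the variance. Two-sided moderated tests gave p-values, adjusted by Benjamini and Hochberg over the genes of a comparison, and genes at an adjusted p below 0.05 were called. A fold change of a gene near 0 depends on the pseudocount of 1, and levels are given beside it where it is large. Groups were those of the labels, and 20 comparisons were made: each inhibitor against no inhibitor within a genotype, the inhibitors against each other, each knockout against wild type of its own experiment at the same treatment, and the interactions of genotype and treatment. Doses differ between inhibitors, at 1 dose each.

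Gene lists were set by function from the annotation: 18 lists, of which 17 were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, both adjusted over all lists and comparisons. Members of the mating type list had values in the inhibitor experiment alone and too few reached the minimum. Annotation terms of 10 to 300 tested genes were compared with the genes called and changed at least 2-fold. The test was a one-sided Fisher's exact test against all tested genes, with or without a term. The text names genes by a fixed rule: the 3 transcription factors in every comparison, all members of both ergosterol lists, of other lists up to 4 members with the largest called change, and per comparison the 6 largest called rises and the 6 largest called falls among annotated genes whose groups do not overlap and whose higher group has a mean of at least 10. Not every gene that this rule admits is printed. The comparisons, the lists' subjects, the naming rule and the first set of alternative settings were chosen before the data were examined.

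The fit was tested on simulated data: values with the spread of these libraries and known changes gave back 80.6% to 97% of genes changed 2-fold and 55.2% to 83.6% of those changed 1.5-fold over 17 comparisons, with 1.7% to 7.6% of calls false. At each size, 66 or 67 genes were changed per comparison, and all others were kept unchanged with noise drawn independently for each gene. In many real comparisons most genes were called, and libraries there can deviate as a whole, which these shares do not cover. Alternatives were median-of-ratios scaling, FPKM as deposited, no filter, a minimum of 5 FPKM, only the compared groups in the fit, a term for the replicate number, each library left out in turn, pseudocounts of 0.1 and 5, the lists with the deleted gene left out, and the authors' deposited comparisons. Each comparison was also repeated on other splits of its libraries, and the interactions again after the mean genotype difference was removed. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. The chromosome positions in the files were not used for any result.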

Results

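RNA abundance was measured by sequencing in mycelia of Neurospora crassa, a filamentous fungus, grown for 12 h in Vogel's minimal medium and then kept for 12 h with or without an inhibitor of sterol synthesis. The 42 libraries form 14 groups of 3 in 3 experiments, each with its own table of FPKM values (mapped fragments corrected for transcript length and library size). The inhibitor experiment holds wild type without inhibitor, with terbinafine (2.5 µg/mL), ketoconazole (1.5 µg/mL) or amorolfine (0.375 µg/mL), and a knockout of ncSR (NCU08594) without inhibitor and with ketoconazole. The sah2 experiment and the atrR experiment each hold wild type and 1 knockout, of sah-2 (NCU04731) or of atrR (NCU01478), without inhibitor and with amorolfine. All 3 genes are named as transcription factors in the study's own description. The steps between low FPKM values gave an estimated depth of 17.0 to 18.3 M fragments per library in the inhibitor experiment, 17.9 to 19.5 M in the sah2 experiment and 13.3 to 14.2 M in the atrR experiment. A log2 fold change is that of scaled FPKM + 1 and is given ± its SE, and a level is a mean of scaled FPKM ± SD over the 3 libraries of a group. Whether the 3 libraries of a group came from separate cultures is not stated, so they may be technical replicates. A gene counts as risen or fallen at an adjusted p below 0.05. The named genes passed that threshold in 186 cases comparing 2 groups, and in 184 of these the 3 libraries of one group all lay above the 3 of the other. Chance alone gives this for 10% of genes not chosen for a difference, whereas these were chosen for passing and in part for groups that do not overlap, so the number describes them and is no test. On the deposited scale the median of all genes lay higher than after scaling by 0.24 to 0.64 log2 in every comparison of an inhibitor with no inhibitor, and all changes below are relative to that median.

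The first question was whether each deleted gene was absent. atrR was listed at 0 FPKM in all 6 atrR knockout libraries. In wild type of that experiment it stood at 18.97, 15.94 and 21.33 FPKM without inhibitor and at 57.1, 56.14 and 55.94 FPKM with amorolfine. ncSR kept some reads in its knockout, at 0.74, 1.28 and 1.23 FPKM without inhibitor and at 0.66, 0.6 and 0.77 FPKM with ketoconazole, against 6.22, 3.77 and 3.78 FPKM and 11.24, 13.04 and 13.69 FPKM in wild type. sah-2 also kept reads in its knockout, at 36.42, 41.95 and 39.11 FPKM without inhibitor and at 15.14, 13.08 and 12.89 FPKM with amorolfine. Wild type held sah-2 at 70.73, 78.12 and 90.48 FPKM without inhibitor and at 53.89, 51.07 and 62.47 FPKM with amorolfine. The scaled means of sah-2 in its knockout were 47.6% of wild type without inhibitor and 25.2% with amorolfine.

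Terbinafine, an inhibitor of squalene epoxidase (ERG1), was compared with no inhibitor in wild type to find the genes that respond to it. Among the 13 late ergosterol genes, those from squalene onward, 4 rose and 6 fell. ERG27, a keto reductase, rose by log2 1.28 ± 0.08, ERG6, the sterol methyltransferase, by 0.58 ± 0.10 and ERG24, a sterol reductase, by 0.44 ± 0.08. ERG25, the sterol methyl oxidase, fell by 1.23 ± 0.17 (from 1268 ± 182 to 543.5 ± 99.8), ERG1 by 0.89 ± 0.22, ERG3 (NCU06207), a sterol desaturase, by 0.86 ± 0.20 and ERG11, the lanosterol demethylase, by 0.62 ± 0.14. Of the 9 early genes, up to squalene, 1 rose and 4 fell. The gene that rose was ERG8, phosphomevalonate kinase, at log2 0.97 ± 0.09. Neither ergosterol list was called as a set (adjusted p = 0.904 and 0.51). Of the design's transcription factors, sah-2 fell by 0.95 ± 0.15 and atrR rose by 0.46 ± 0.08. ncSR was at log2 0.45 ± 0.15 (adjusted p = 0.0163) with overlapping groups, and its call ended without wild type control replicate 2 (0.35, adjusted p = 0.0807) or 3 (0.34, adjusted p = 0.0763), without terbinafine replicate 2 (0.41, adjusted p = 0.0521), and with only the compared groups in the fit (adjusted p = 0.07).

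Outside sterol synthesis, 6 of 8 transporters linked to drug efflux rose under terbinafine and 2 fell. NCU09975, annotated as a multidrug resistance protein, rose from 20.45 ± 1.09 to 312.1 ± 22 (log2 3.87 ± 0.10), and NCU03776, an ABC transporter, rose by 1.73 ± 0.10. The transporter list was called up (adjusted p = 0.0367, and adjusted p = 0.39 with an estimated correlation). Cell wall genes rose in 19 of 29 cases and fell in 1, with the chitin synthase gene chs-1 at log2 1.01 ± 0.08. That list was called up (adjusted p = 0.0142, and adjusted p = 0.456 with an estimated correlation). Of 45 cytosolic ribosomal protein genes, 42 fell and 1 rose, with po, a gene of the ribosomal stalk, at log2 −1.37 ± 0.08. The ribosomal list was called down (adjusted p = 1.24e-16, and adjusted p = 0.433 with an estimated correlation). Heat shock protein genes fell in 12 of 17 cases and rose in 2, with hsp60 at log2 −1.43 ± 0.17, and the list was called down (adjusted p = 0.0434, and adjusted p = 0.627 with an estimated correlation). As set, the heat shock list holds NCU07414, whose product is annotated as a proline iminopeptidase. All 4 nitrate assimilation genes fell, among them nit-3, nitrate reductase, at log2 −2.70 ± 0.19 and nit-6, nitrite reductase, at −1.76 ± 0.19, although the list was not called (adjusted p = 0.0523). The largest changes by the naming rule included rises of NCU08176, a pectate lyase, from 0.647 ± 0.838 to 81.74 ± 10.4, of NCU06792, a mannosylphosphate transferase, from 0.160 ± 0.115 to 57.17 ± 2.3, and of mig-9, annotated as a pyridoxal reductase, from 100.8 ± 4.54 to 3128 ± 354. cat-2, a catalase-peroxidase, rose by log2 2.68 ± 0.18, and NCU04697, a cyanide hydratase, fell by 4.53 ± 0.50. Of 7806 genes tested, 5406 passed, 2732 higher and 2674 lower. The share higher was 50.5%, and 71.2% on the deposited scale.

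Ketoconazole, an inhibitor of ERG11, was compared with no inhibitor in wild type. ERG6 rose from 98.56 ± 15.2 to 1727 ± 58.3 (log2 4.13 ± 0.10), ERG24 from 69.5 ± 8.07 to 640.3 ± 12.1 (3.19 ± 0.08) and ERG11 from 211.3 ± 42 to 1710 ± 114 (3.03 ± 0.14). ERG2, the sterol isomerase, rose by 1.02 ± 0.09 and ERG5, a sterol desaturase of the cytochrome P450 family, by 0.90 ± 0.10. In all, 6 of 13 late ergosterol genes rose and 2 fell, ERG1 being among those that fell, at −1.22 ± 0.22. ERG25 was at log2 0.07 ± 0.17 and was not called. The late list as a set was not called (adjusted p = 0.166), and neither was the early list (adjusted p = 0.0711), in which 7 of 9 genes fell and 0 rose. With no filter camera did call the early list (adjusted p = 0.0372). ncSR rose by 1.08 ± 0.15 and atrR by 0.94 ± 0.08, and sah-2 fell by 1.09 ± 0.15.

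The largest rise under ketoconazole was that of NCU00606, annotated as a short-chain alcohol dehydrogenase, from 0.276 ± 0.183 to 1415 ± 88.3 (log2 10.12 ± 0.16). ci-1 (NCU05001), annotated as an ent-kaurene oxidase, rose from 10.57 ± 0.884 to 3919 ± 189. NCU07819 and NCU07610, both annotated as taurine dioxygenases, rose by log2 7.39 ± 0.15 and 7.10 ± 0.15. Among the drug efflux transporters 6 of 8 rose and 0 fell, with NCU07546 at 2.16 ± 0.09, NCU05591 at 2.15 ± 0.18 and NCU03776 at 1.98 ± 0.10. That list was called up (adjusted p = 0.0359, and adjusted p = 0.39 with an estimated correlation). Genes of the fatty acid synthesis list fell in 9 of 12 cases and rose in 3. Those that fell included the fatty acid synthase genes cel-1 at log2 −2.58 ± 0.12 and cel-2 at −2.51 ± 0.12. Here and below this list includes NCU06895, whose product is annotated as a cytochrome P450, and NCU06786, annotated as a ribosomal protein. The list was called down (adjusted p = 0.0232, and adjusted p = 0.433 with an estimated correlation). Ribosomal protein genes fell in 42 of 45 cases and rose in 1, with crp-4 at −1.43 ± 0.08 (adjusted p = 3.7e-16, and adjusted p = 0.434 with an estimated correlation). Heat shock genes fell in 14 of 17 cases and rose in 2 (adjusted p = 0.012, and adjusted p = 0.527 with an estimated correlation), and cell wall genes rose in 18 of 29 and fell in 1 (adjusted p = 0.0232, and adjusted p = 0.456 with an estimated correlation). In the list of 8 genes of protein folding in the endoplasmic reticulum 5 rose and 1 fell, with the disulfide isomerase genes mig-2 at 1.10 ± 0.17 and NCU09223 at 1.18 ± 0.08, and the list was not called (adjusted p = 0.193). Here and below the folding list includes NCU08897, annotated as SEC61 subunit alpha, a protein transport protein. The photoreceptor gene vvd rose by 2.54 ± 0.40, am, the NADP-dependent glutamate dehydrogenase gene, fell by 3.37 ± 0.15 and nit-3 by 2.82 ± 0.19. Of the genes tested, 5791 passed, 3006 higher and 2785 lower. The higher ones made up 51.9%, and 68.1% on the deposited scale.

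Amorolfine, an inhibitor of ERG24 and ERG2, was compared with no inhibitor in wild type of the inhibitor experiment. ERG24 rose from 69.5 ± 8.07 to 4437 ± 80.4 (log2 5.98 ± 0.08), ERG2 from 219.5 ± 36.2 to 1390 ± 71.8 (2.67 ± 0.09), ERG3 (NCU06207) by 1.92 ± 0.20 and ERG25 by 1.59 ± 0.17. ERG1 fell by 1.17 ± 0.22 and ERG11 by 0.80 ± 0.14. In the late list 5 of 13 genes rose and 6 fell, with a median of −0.11 and a mean of 0.65, and the set was not called (adjusted p = 0.904, direction up). In the early list 2 of 9 rose and 5 fell (adjusted p = 0.263). atrR rose by 0.86 ± 0.08, ncSR by 0.56 ± 0.15 with overlapping groups, and sah-2 fell by 0.55 ± 0.15. The call of sah-2 ended on the deposited scale (−0.22, adjusted p = 0.14).

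**Figure D1:**
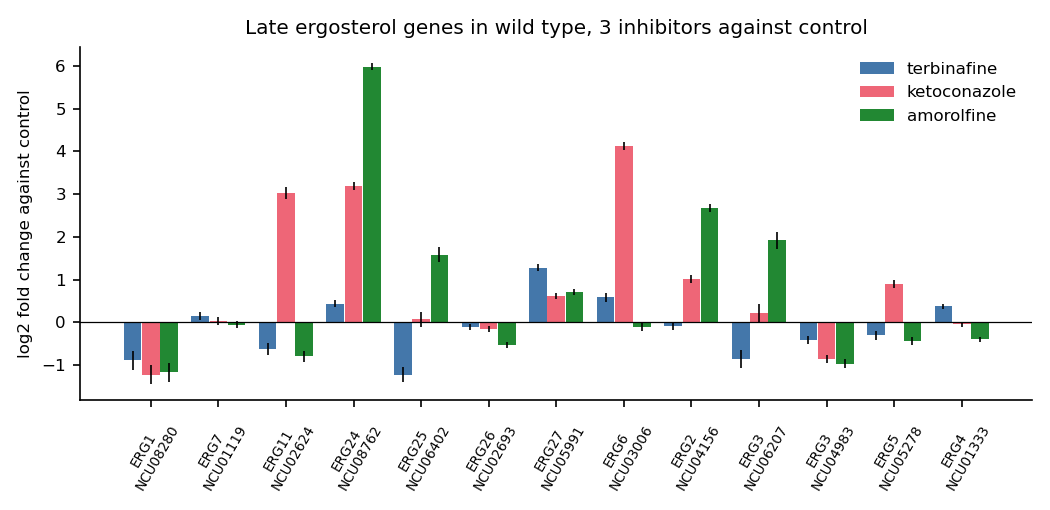
Log2 fold change against no inhibitor (y axis) of the 13 late ergosterol genes (x axis) in wild type; bars are fitted values under terbinafine, ketoconazole and amorolfine, and lines their SE (3 libraries per group). ERG11 and ERG6 stand highest under ketoconazole, at 3.03 and 4.13, and ERG24 under amorolfine, at 5.98.

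The gene with the largest rise under amorolfine was NCU05649, which encodes a protein with an RTA1 domain, from 3.238 ± 0.97 to 2489 ± 50.7 (log2 9.22 ± 0.12). NCU05852, a glucuronan lyase, rose by 7.20 ± 0.19 and NCU06153, a monooxygenase, by 6.89 ± 0.10. Conidiation genes rose in 7 of 9 cases and fell in 0, with con-8 at 4.71 ± 0.19 and con-10 at 3.54 ± 0.22, and the list was called up (adjusted p = 0.0155, and adjusted p = 0.425 with an estimated correlation). Here and below this list includes al-1, al-2 and al-3, carotenoid genes that are also counted among the light-induced genes. Drug efflux transporters rose in 6 of 8 cases and fell in 0, with NCU03776 at 2.47 ± 0.10 and NCU08439 at 1.79 ± 0.20 (adjusted p = 0.0321, and adjusted p = 0.39 with an estimated correlation). Of 7 genes of iron and siderophore metabolism 5 rose and 2 fell, with NCU07117, an ornithine oxygenase, at 2.29 ± 0.11, and the list was not called (adjusted p = 0.176). Genes of the fatty acid synthesis list fell in 9 of 12 cases and rose in 1, with cel-2 at −2.42 ± 0.12 and cel-1 at −2.21 ± 0.12 (adjusted p = 0.0102, and adjusted p = 0.39 with an estimated correlation). All 4 nitrate assimilation genes fell, with nit-3 at −3.14 ± 0.19 (adjusted p = 0.0414, and adjusted p = 0.39 with an estimated correlation). am fell from 1739 ± 242 to 118.3 ± 17.1. Ribosomal protein genes fell in 42 of 45 cases and rose in 2, with po at −2.05 ± 0.08 (adjusted p = 3.5e-18, and adjusted p = 0.433 with an estimated correlation). Heat shock genes fell in 14 of 17 cases and rose in 2 (adjusted p = 0.0164, and adjusted p = 0.556 with an estimated correlation). In the cell wall list 14 of 29 rose and 3 fell, with chit-1, a chitinase gene, at −2.10 ± 0.24, and the set was not called (adjusted p = 0.219). In total 5703 genes passed, 2992 higher and 2711 lower. The share higher was 52.5%, and 71.2% on the deposited scale.

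The same wild type libraries without inhibitor served all 3 inhibitors. A total of 1930 genes rose under every inhibitor, against 403.2 for independent responses, and 1976 fell under every one, against 331.3. Among them, NCU03776, atrR and ERG27 rose and sah-2, ERG1, nit-3 and po fell. With a 2-fold minimum 395 rose and 425 fell. On the deposited scale 3147 rose and 1177 fell under every one. A further 359 genes were called higher under some inhibitor and lower under another, not necessarily with a call under every one, ERG11 among them. Across genes, which are not independent replicates, the responses correlated at r = 0.751 for terbinafine and ketoconazole, 0.853 for terbinafine and amorolfine and 0.809 for ketoconazole and amorolfine. Shared control libraries alone raise such values: groups simulated without any change gave r from 0.492 to 0.5, and limma called 0 genes in all 3 comparisons there in each of 20 simulations, with 0.0167 genes per single comparison. With so few genes called at all, this 0 cannot show how far the shared controls raised the overlap. The numbers for independent responses do not allow for shared controls either. The covariance of the responses, which unlike r keeps their size, was 0.639, 0.694 and 0.844 for these pairs in the same order. The simulated groups gave 0.01, 0.011 and 0.011. At the spread between these libraries, shared controls alone thus gave little of the covariance. A deviation common to all libraries of the control group was not simulated. Terms held by more 2-fold genes than chance (one-sided Fisher's exact test) included the extracellular region among the rises, with 46 of 121 genes under terbinafine (10.4 expected, adjusted p = 5.88e-16), and the structural constituents of the ribosome among the falls, with 125 of 145 under amorolfine (17.1 expected, adjusted p = 1.44e-93). Monooxygenase activity was called among the rises under ketoconazole, with 31 of 98 genes (11.8 expected, adjusted p = 0.000204), and under amorolfine, with 33 of 98 (10.9 expected, adjusted p = 1.7e-06).

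Direct comparisons of the inhibitors show where the responses differ, at doses that differ as well. ERG11 was higher under ketoconazole than under terbinafine by log2 3.65 ± 0.14 and than under amorolfine by 3.82 ± 0.14, and ERG6 by 3.54 ± 0.10 and 4.24 ± 0.10. ERG24 was highest under amorolfine, by 5.54 ± 0.08 over terbinafine, and ketoconazole lay below amorolfine by a log2 value of −2.79 ± 0.08. ERG2 was higher under amorolfine than under terbinafine by 2.76 ± 0.09, ERG25 by 2.81 ± 0.17 and NCU07117 by 2.80 ± 0.11. NCU00606 was higher under ketoconazole than under terbinafine by 9.79 ± 0.16 and than under amorolfine by 9.74 ± 0.16, while NCU05649 stood at −5.81 ± 0.12 under ketoconazole relative to amorolfine and NCU09975 at −3.17 ± 0.10 under amorolfine relative to terbinafine. ncSR was higher under ketoconazole than under terbinafine by 0.63 ± 0.15. Folding genes of the endoplasmic reticulum were higher in 7 of 8 cases under ketoconazole than under terbinafine and lower in 0, with mig-2 at 2.34 ± 0.17 and grp78 at 1.08 ± 0.08 (adjusted p = 0.000494, and adjusted p = 0.39 with an estimated correlation). They were higher in 7 of 8 cases also relative to amorolfine, and in 8 of 8 adjusted over the list alone, with mig-2 at 2.54 ± 0.17 (adjusted p = 0.000432, and adjusted p = 0.39 with an estimated correlation). Siderophore genes were higher under amorolfine than under terbinafine in 6 of 7 cases and lower in 1 (adjusted p = 0.00297, and adjusted p = 0.39 with an estimated correlation). Genes of the fatty acid synthesis list were lower under amorolfine than under terbinafine in 8 of 12 cases and higher in 1, with cel-2 at −1.75 ± 0.12 (adjusted p = 0.00183, and adjusted p = 0.39 with an estimated correlation). In the late ergosterol list 7 of 13 genes were higher and 3 lower under ketoconazole than under terbinafine, and the set was not called (adjusted p = 0.0515). Camera did call this set on the deposited scale (adjusted p = 0.0359), with no filter (adjusted p = 0.0372) and with a pseudocount of 0.1 (adjusted p = 0.0463). The genes called numbered 3573 for ketoconazole and terbinafine (1851 higher, 1722 lower), 3494 for ketoconazole and amorolfine (1906 higher, 1588 lower) and 3536 for amorolfine and terbinafine (1750 higher, 1786 lower). On the deposited scale the larger side turned in each, with 1677 higher and 1894 lower, 1591 and 1873, and 1853 and 1617.

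The ncSR knockout was compared with wild type without inhibitor to see how the strain without this gene differs before any drug. ERG11 was at log2 0.07 ± 0.14 and was not called. ERG1 was lower in the knockout at −0.90 ± 0.22 and ERG24 higher by 0.45 ± 0.08. In the late list 1 of 13 genes was higher and 6 lower, and 8 lower adjusted over the list alone, and the set was not called (adjusted p = 0.0536). With no filter camera did call this late set (adjusted p = 0.0358). In the early list 5 of 9 were lower, and 6 adjusted over the list alone, and 0 were higher (adjusted p = 0.0357, and adjusted p = 0.456 with an estimated correlation). cmt, which encodes copper metallothionein, rose from 444.4 ± 39.5 to 3497 ± 166 (log2 2.98 ± 0.14), and NCU05586, a malate or lactate dehydrogenase, fell by 2.93 ± 0.20. al-1, a carotenoid synthesis gene, fell by 2.44 ± 0.39 and the clock gene frq by 1.53 ± 0.17. het-6, a heterokaryon incompatibility gene, was listed at 0 FPKM in the 3 wild type libraries without inhibitor and at 8.86, 9.38 and 11.2 FPKM in the knockout. With ketoconazole it was again listed at 0 in the 3 wild type libraries and at 12.12, 13.45 and 12.3 FPKM in the knockout. The labels do not say whether a knockout shares its strain background with the wild type, so a difference between genotypes, here and below, may come from other loci. atrR was at −0.07 ± 0.08 and was not called. sah-2 was lower at −0.44 ± 0.15 (adjusted p = 0.0375), and its call ended on the deposited scale (adjusted p = 0.0754), without wild type control replicate 1 (−0.46, adjusted p = 0.0708) or 2 (−0.39, adjusted p = 0.124) and without knockout control replicate 1 (−0.42, adjusted p = 0.0859) or 3 (−0.38, adjusted p = 0.128). Ribosomal protein genes were lower in 33 of 45 cases, and in 38 adjusted over the list alone, and higher in 0 (adjusted p = 8.01e-09, and adjusted p = 0.513 with an estimated correlation). Of the genes tested, 2011 passed, 998 higher and 1013 lower, and 657 passed with only the compared groups in the fit, 65.3% of them higher. The authors' deposited comparison held 1101, 61.0% of them higher, so that the even split did not hold there. The share higher was 49.6%, and 73.9% on the deposited scale.

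With ketoconazole, the knockout of ncSR lacked the rise of the gene of the drug's target. ERG11 stood at 119.9 ± 18.9 in the knockout against 1710 ± 114 in wild type (log2 −3.83 ± 0.14), and ERG6 at 104.8 against 1727 ± 58.3 (−4.03 ± 0.10). ERG24 did not follow, at 620.4 ± 64.9 against 640.3 ± 12.1 (−0.05 ± 0.08, not called). ERG5 was lower at −0.47 ± 0.10. In all, 9 of 13 late ergosterol genes were lower and 0 higher (adjusted p = 0.000788, and adjusted p = 0.39 with an estimated correlation). NCU00606 stood at 0.422 ± 0.145 in the knockout against 1415 ± 88.3 in wild type. All 8 folding genes of the endoplasmic reticulum were lower, with mig-2 at −1.41 ± 0.17 and grp78 at −0.74 ± 0.08 (adjusted p = 1.86e-06, and adjusted p = 0.39 with an estimated correlation). Of the transporters linked to drug efflux 1 was higher and 4 lower, and 2 higher adjusted over the list alone, with NCU03776 at 0.65 ± 0.10, and the list was not called (adjusted p = 0.593). NCU05649 was higher in the knockout, at 419.1 ± 13 against 43.69 ± 4.98, and cmt at 3185 ± 208 against 406.7 ± 60.1. ncSR itself was at log2 −3.05 ± 0.15. Of the genes tested, 2457 passed, 1056 higher and 1401 lower. The higher ones made up 43.0%, and 68.8% on the deposited scale.

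Within the ncSR knockout, ketoconazole was compared with no inhibitor. ERG24 rose from 95.16 ± 6.55 to 620.4 ± 64.9 (log2 2.69 ± 0.08), ERG6 rose by 0.54 ± 0.10 and ERG11 fell by 0.87 ± 0.14. NCU07819 rose by 7.03 ± 0.15 and ci-1 by 5.90 ± 0.08, while NCU00606 was at 0.08 ± 0.16 and was not called. A total of 5682 genes passed, 2993 higher and 2689 lower, and the share higher was 52.7%, and 70.6% on the deposited scale. Across genes, which are not independent replicates, the ketoconazole responses of both genotypes correlated at r = 0.905. The interaction tests whether ketoconazole acted differently in the knockout, and it called 887 genes, 315 with a higher and 572 with a lower response in the knockout. Its largest terms included NCU00606 (log2 −10.05 ± 0.22), NCU00732, annotated as a trichothecene hydroxylase (−5.13 ± 0.35), ERG11 (−3.90 ± 0.20), ERG6 (−3.59 ± 0.14) and ci-1 (−2.51 ± 0.11). ERG24 differed less, at −0.50 ± 0.12. In the late ergosterol list 4 of 13 genes had a lower response, and 0 a higher one, or 1 adjusted over the list alone (adjusted p = 0.0293, and adjusted p = 0.436 with an estimated correlation). In the folding list 7 of 8 had a lower response and 0 a higher one (adjusted p = 3.6e-06, and adjusted p = 0.39 with an estimated correlation). Of the 4 clock and light genes 2 had a higher response and 4 adjusted over the list alone (adjusted p = 0.00463, and adjusted p = 0.39 with an estimated correlation). With only the compared groups in the fit the interaction called 574 genes.

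**Figure D2:**
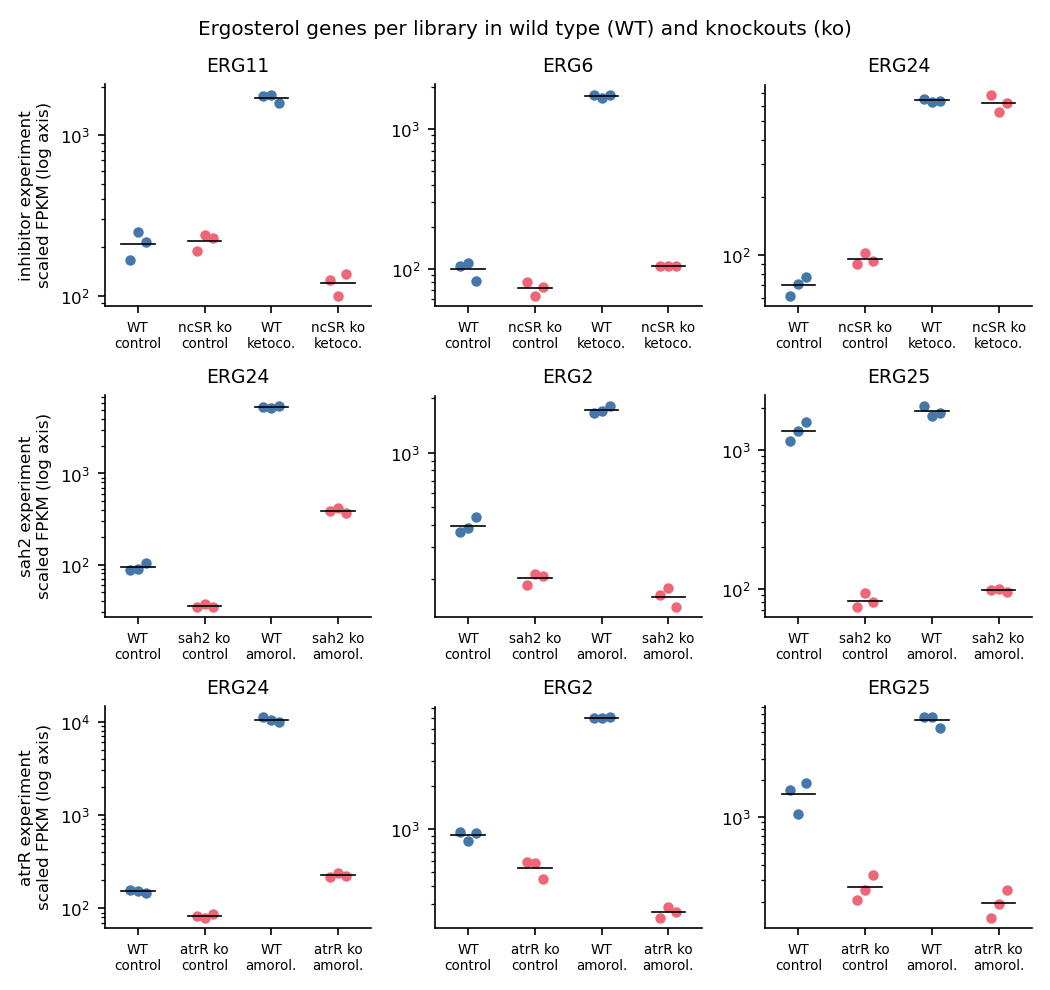
Scaled FPKM (y axis, log scale) of 3 ergosterol genes per experiment in wild type (blue) and knockout (red), without inhibitor and with ketoconazole (top panels) or amorolfine (other panels); points are libraries and lines the group means. ERG11 stands at 1710 in wild type and 119.9 in the ncSR knockout with ketoconazole, and ERG24 at 10480 in wild type and 225.7 in the atrR knockout with amorolfine.

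In the sah2 experiment, amorolfine was compared with no inhibitor in wild type. ERG24 rose from 92.92 ± 8.5 to 5409 ± 141 (log2 5.85 ± 0.07), ERG2 by 2.13 ± 0.10 and ERG25 by 0.48 ± 0.11, and ERG1 fell by 2.49 ± 0.25. In the late list 6 of 13 genes rose and 4 fell, and the set was not called (adjusted p = 0.473). sah-2 fell by 1.27 ± 0.12 and ncSR rose by 1.19 ± 0.09. atrR was at 0.14 ± 0.08 and was not called (adjusted p = 0.113), but was called on the deposited scale, at 0.88 (adjusted p = 1.64e-07). NCU05649 rose from 4.163 ± 0.534 to 2200 ± 68.7. Genes induced by light were lower here: vvd fell from 282.3 ± 58.4 to 4.996 ± 2.42 and al-1 from 347.5 ± 57.5 to 6.962 ± 3.64. The hydrophobin gene eas fell by 4.66 ± 0.55, while con-8 rose by 2.10 ± 0.38. The conidiation list, with 2 of 9 risen and 5 fallen, was not called (adjusted p = 0.319). The cellulase list rose in 5 of 6 cases and fell in 0 (adjusted p = 0.0302, and adjusted p = 0.433 with an estimated correlation), and ribosomal protein genes fell in 43 of 45 and rose in 1 (adjusted p = 5.59e-18, and adjusted p = 0.39 with an estimated correlation). Of 7886 genes tested, 6074 passed, 3060 higher and 3014 lower. The share higher was 50.4%, and 80.7% on the deposited scale.

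The sah2 knockout was compared with wild type without inhibitor to see which genes differ without this factor, a homologue of the sterol regulatory proteins called SREBP. ERG25 stood at 82 ± 9.55 in the knockout against 1369 ± 215 in wild type (log2 −4.04 ± 0.11), ERG3 (NCU06207) at 35.46 ± 4.1 against 411.3 ± 40.6 (−3.50 ± 0.13) and ERG1 at 52.67 ± 4.11 against 291 ± 33.8 (−2.44 ± 0.25). ERG11 was lower at −1.68 ± 0.15, ERG24 at −1.39 ± 0.07 and ERG2 at −0.96 ± 0.10. Altogether 9 of 13 late ergosterol genes were lower and 0 higher (adjusted p = 0.000183, and adjusted p = 0.39 with an estimated correlation). In the early list 2 of 9 were higher, or 3 adjusted over the list alone, and 4 lower, with ERG8 at 1.06 ± 0.07, and the set was not called (adjusted p = 0.493). The alternative oxidase genes rose, aod-3 from 0.754 ± 0.258 to 168.5 ± 61.4 and aod-1 from 127.9 ± 14.5 to 3810 ± 586. acu-6, which encodes phosphoenolpyruvate carboxykinase, rose by 5.21 ± 0.13, and NCU06719 fell by 6.38 ± 0.55. Heat shock genes were higher in 11 of 18 cases, or 12 adjusted over the list alone, and lower in 2, with hsp30 at 2.31 ± 0.21 and hsp98 at 2.15 ± 0.10 (adjusted p = 0.0128, and adjusted p = 0.501 with an estimated correlation). Siderophore genes were lower in 5 of 7 cases and higher in 1 (adjusted p = 0.0177, and adjusted p = 0.39 with an estimated correlation). Of 95 genes of amino acid synthesis 36 rose at least 2-fold, with 5.8 expected (adjusted p = 3.74e-17). atrR was higher by 0.47 ± 0.08, ncSR was at 0.01 ± 0.09 and was not called, and sah-2 itself was at −1.05 ± 0.12. A total of 4280 genes passed, 2130 higher and 2150 lower. The share higher was 49.8%, and 56.5% on the deposited scale.

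With amorolfine the sah2 knockout held ERG24 at 391.2 ± 26.7 against 5409 ± 141 in wild type (log2 −3.79 ± 0.07), ERG25 at 97.32 ± 2.82, or −4.27 ± 0.11 relative to wild type, and ERG2 at 159.5 ± 19.2 against 1731 ± 88.7 (−3.44 ± 0.10). ERG3 (NCU06207) was lower at −4.51 ± 0.13 and ERG3 (NCU04983) at −2.45 ± 0.11. Of the 13 late genes 8 were lower and 1 higher (adjusted p = 0.000166, and adjusted p = 0.39 with an estimated correlation). The KEGG term steroid biosynthesis held 7 of its 34 genes among those lower by at least 2-fold, with 0.8 expected (adjusted p = 0.00375). al-1 was higher in the knockout, at 372.8 ± 144 against 6.962 ± 3.64, and vvd at 248.3 ± 73 against 4.996 ± 2.42, the wild type libraries with amorolfine being those in which these genes were low. The conidiation list was called up, with 6 of 9 higher and 0 lower, or 1 lower adjusted over the list alone (adjusted p = 0.0232, and adjusted p = 0.501 with an estimated correlation), as was the clock and light list, with 4 of 4 higher (adjusted p = 0.00555, and adjusted p = 0.39 with an estimated correlation). acu-6 was higher by 6.43 ± 0.13 and atrR by 0.56 ± 0.08, and ncSR was at −0.13 ± 0.09 and was not called. sah-2 itself was at −1.90 ± 0.12. In all 3719 genes passed, 1771 higher and 1948 lower.

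Within the sah2 knockout amorolfine still raised ERG24, from 34.87 ± 1.5 to 391.2 ± 26.7 (log2 3.45 ± 0.07), and NCU05649, from 5.851 ± 1.44 to 4028 ± 215. ERG2 fell by 0.34 ± 0.10, but on the deposited scale stood at 0.36 (adjusted p = 0.00316), so that its direction depended on the scaling. aod-3 fell from 168.5 ± 61.4 to 1.605 ± 0.299. Of the genes tested, 6358 passed, 3219 higher and 3139 lower, and the share higher was 50.6%, and 74.1% on the deposited scale. The interaction of genotype and amorolfine called 3692 genes, 1727 with a higher and 1965 with a lower response in the knockout. ERG24 (−2.40 ± 0.10), ERG2 (−2.47 ± 0.14), ERG3 (NCU04983, −1.83 ± 0.16) and ERG3 (NCU06207, −1.01 ± 0.18) had a lower response, and ERG1 (1.39 ± 0.36) and ERG11 (0.93 ± 0.21) a higher one. ERG25 was at −0.23 ± 0.16 and was not called. As a set the late genes, with 4 higher and 4 lower, were not called (adjusted p = 0.524). al-1 (6.45 ± 0.43) and vvd (5.57 ± 0.40) had a higher and aod-3 (−5.84 ± 0.28) a lower response. Among genes of amino acid synthesis 51 of 95 had a response lower by at least 2-fold, with 5.9 expected (adjusted p = 2.96e-34). Across genes the responses of both genotypes correlated at r = 0.816.

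In the atrR experiment, amorolfine raised ERG24 in wild type from 152.8 ± 5.4 to 10480 ± 762 (log2 6.09 ± 0.08), ERG2 from 913.1 ± 70.7 to 6007 ± 92.8 (2.72 ± 0.11), ERG3 (NCU06207) by 2.72 ± 0.31 and ERG25 by 2.06 ± 0.25. Of the 13 late genes 6 rose and 1 fell (adjusted p = 0.0434, and adjusted p = 0.456 with an estimated correlation). atrR rose by 1.23 ± 0.11 and ncSR by 0.41 ± 0.11. sah-2 rose by 0.66 ± 0.21, a call that ended without wild type control replicate 2 (0.49, adjusted p = 0.064) and without amorolfine replicate 1 (0.58, adjusted p = 0.0623) or 2 (0.57, adjusted p = 0.0663). The list of 6 regulators of sterol synthesis and azole response, in which 5 rose and 0 fell, was called up (adjusted p = 0.0232, and adjusted p = 0.433 with an estimated correlation). NCU05649 rose by 9.25 ± 0.29 and con-8 by 5.53 ± 0.40. The conidiation list rose in 6 of 8 cases and fell in 0 (adjusted p = 0.0232, and adjusted p = 0.456 with an estimated correlation). Of 7758 genes tested, 4859 passed, 2336 higher and 2523 lower. The higher ones made up 48.1%, and 72.3% on the deposited scale.

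Amorolfine in wild type was thus measured in 3 experiments. Of 7254 genes tested in all of them, 1428 rose and 1615 fell in each, against 324.7 and 337.5 for independent responses. ERG24, ERG2, ERG25 and NCU05649 rose in each, and ncSR did so as well. A further 728 were called higher in some experiment and lower in another, not necessarily with a call in each, sah-2 among them. With a 2-fold minimum 336 rose and 440 fell, and on the deposited scale 2758 rose and 679 fell. Across genes, which are not independent replicates, the responses correlated at r = 0.72 for the inhibitor and sah2 experiments, 0.75 for the inhibitor and atrR experiments and 0.717 for the sah2 and atrR experiments.

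The atrR knockout was compared with wild type without inhibitor. ERG25 stood at 263 ± 64 in the knockout against 1541 ± 448 in wild type (log2 −2.53 ± 0.25), ERG3 (NCU04983) at 79.63 ± 11.4 against 227.2 ± 51.5 (−1.48 ± 0.15) and ERG24 at 82.11 ± 3.96 against 152.8 ± 5.4 (−0.89 ± 0.08). Of the 13 late genes 5 were lower and 0 higher, or 1 higher adjusted over the list alone (adjusted p = 0.00129, and adjusted p = 0.39 with an estimated correlation). map-1, which encodes a mitochondrial matrix protease and carries the locus number next to atrR, was higher, at 165.5 ± 5.55 against 69.96 ± 8.42. ncSR was at 0.21 ± 0.11 and was not called. sah-2 was lower at −0.93 ± 0.21 (adjusted p = 0.0464), and its call ended without wild type control replicate 1 (−0.83, adjusted p = 0.155) or 3 (−0.86, adjusted p = 0.157), without knockout control replicate 1 (−0.83, adjusted p = 0.145) or 2 (−0.86, adjusted p = 0.17), with no filter (adjusted p = 0.0581), with a replicate block (adjusted p = 0.058) and with only the compared groups (adjusted p = 0.248). The ribosomal list was called down (adjusted p = 0.00107, and adjusted p = 0.698 with an estimated correlation), with a median of −0.14 that turned to 0.05 on the deposited scale. The regulators, with the deleted atrR counted, were lower in 2 of 6 cases, or 3 adjusted over the list alone, and higher in 0 (adjusted p = 0.0214, and adjusted p = 0.433 with an estimated correlation). That call ended with atrR left out, where 1 of 5 was lower, or 2 adjusted over the list alone (adjusted p = 0.366). Only 218 genes passed, 107 higher and 111 lower, and this count rested on single libraries: it was 10, 1948 and 21 without wild type control replicate 1, 2 or 3, and 13, 22 and 1200 without knockout control replicate 1, 2 or 3. Where leaving out a library lowered the count, more genes were lower: 3 higher and 7 lower, 6 and 15, 3 and 10, and 5 and 17, in the order given. In the authors' deposited comparison, 57 genes were higher and 174 lower. The count was 8 with only the compared groups in the fit, which also ended the call of ERG3 (adjusted p = 0.12), 92 with no filter, 108 with a replicate block and 1934 on the deposited scale, where the share higher was 89.9% in place of 49.1%.

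With amorolfine the atrR knockout held ERG24 at 225.7 ± 12.7 against 10480 ± 762 in wild type (log2 −5.53 ± 0.08), ERG2 at 263.9 ± 24.2 against 6007 ± 92.8 (−4.51 ± 0.11) and ERG25 at 195.9 ± 52.8 against 6266 ± 711 (−5.02 ± 0.25). ERG3 was lower at both loci, NCU06207 at −5.01 ± 0.31 and NCU04983 at −3.76 ± 0.15. Of the 13 late genes 8 were lower and 0 higher (adjusted p = 9.6e-05, and adjusted p = 0.39 with an estimated correlation). sah-2 was lower at −2.29 ± 0.21 and ncSR higher by 0.58 ± 0.11. All 8 folding genes of the endoplasmic reticulum were lower (adjusted p = 9.23e-05, and adjusted p = 0.39 with an estimated correlation). Of 9 genes of heme synthesis 6 were lower and 0 higher, with the aminolevulinate synthase gene NCU06189 at −2.62 ± 0.12 (adjusted p = 0.00504, and adjusted p = 0.39 with an estimated correlation). Among the 7 drug efflux transporters measured, 2 were lower, NCU08439 (−1.37 ± 0.11) and NCU05591, and 2 higher, with NCU03776 at 0.89 ± 0.07, and the list was not called (adjusted p = 0.62). Conidiation genes were lower in 5 of 8 cases and higher in 0, with the regulator gene fl at −1.81 ± 0.15 (adjusted p = 0.0102, and adjusted p = 0.436 with an estimated correlation). NCU01057 and NCU07819, both annotated as taurine dioxygenases, were higher by 4.09 ± 0.27 and 4.08 ± 0.19. A total of 2878 genes passed, 1207 higher and 1671 lower, and the share higher was 41.9%, and 77.2% on the deposited scale.

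Within the atrR knockout amorolfine raised ERG24 from 82.11 ± 3.96 to 225.7 ± 12.7 (log2 1.45 ± 0.08), while ERG2 fell from 541.3 ± 82 to 263.9 ± 24.2 and ERG25 was at −0.43 ± 0.25 and was not called. NCU05649 rose by 9.51 ± 0.29 and NCU07819 by 4.77 ± 0.19. In total 5480 genes passed, 2641 higher and 2839 lower, and the share higher was 48.2%, and 69.8% on the deposited scale. The interaction of genotype and amorolfine called 1564 genes, 582 with a higher and 982 with a lower response in the knockout. ERG24 (−4.64 ± 0.11), ERG2 (−3.75 ± 0.16), ERG3 (NCU06207, −3.18 ± 0.44), ERG25 (−2.49 ± 0.36), ERG3 (NCU04983, −2.28 ± 0.21) and sah-2 (−1.36 ± 0.30) had a lower response. NCU01057 (4.57 ± 0.38) and NCU07819 (4.57 ± 0.27) had a higher one. In the late list 5 of 13 genes had a lower response, or 7 adjusted over the list alone, and 0 a higher one (adjusted p = 0.00014, and adjusted p = 0.39 with an estimated correlation). In the folding list 6 of 8 had a lower response, or 7 adjusted over the list alone, and 0 a higher one (adjusted p = 2.75e-05, and adjusted p = 0.39 with an estimated correlation). The count was 1017 without wild type control replicate 3, 897 without knockout control replicate 2 and 993 without knockout amorolfine replicate 1. The share with a higher response was 37.2%, and 50.2% on the deposited scale. Across genes the responses of both genotypes correlated at r = 0.867.

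The lists not yet given in full had the following results under terbinafine, ketoconazole and amorolfine in the inhibitor experiment. Of 18 sphingolipid genes 11, 4 and 3 rose and 3, 6 and 8 fell, and the list was not called (adjusted p = 0.238, 0.643 and 0.508). Of 23 genes of the oxidative stress response 5, 11 and 6 rose and 10, 9 and 9 fell, or 10 under ketoconazole adjusted over the list alone (adjusted p = 0.51, 0.954 and 0.643), the ketoconazole set having a median of 0.28, a mean of 0.02 and a test direction of down. Heme genes rose in 2, 4 and 3 of 9 cases and fell in 6, 4 and 6 (adjusted p = 0.302, 0.968 and 0.283), with a median of 0.25, a mean of −0.04 and a test direction of down under ketoconazole. Of the 7 cellulase genes measured 5, 4 and 5 rose and 0 fell (adjusted p = 0.0601, 0.0873 and 0.0731), and of the 4 clock and light genes 1, 2 and 1 rose and 1, 0 and 0 fell (adjusted p = 0.732, 0.377 and 0.647). Siderophore genes rose in 0 and 4 of 7 cases and fell in 4 and 1 under terbinafine and ketoconazole, 2 having risen under terbinafine adjusted over the list alone (adjusted p = 0.381 and 0.462). The regulators rose in 4 of 6 cases and fell in 2 under each inhibitor (adjusted p = 0.25, 0.344 and 0.325). Of the 3 mat A genes of the mating type list only matA-1 reached 1 FPKM, at 1.63 to 58.47 FPKM in all 18 libraries of the inhibitor experiment, with matA-2 at up to 0.06 and matA-3 at up to 0.18 FPKM there, and the list was not tested as a set. Over all 20 comparisons and 17 lists tested, 103 of 340 pairs were called, 37 up and 66 down. With an estimated correlation limma's camera called 0 of the 340, with a lowest adjusted p of 0.39 and 39 pairs at an unadjusted p below 0.05. Where no count adjusted over the list alone is given, it equalled that over all genes tested. Median and mean differed in sign in 38 pairs and median and test in 24, none of these being called.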

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

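The tests on light-induced genes, on sah-2 reads, on wild type control replicate 2 of the atrR experiment and on other splits of the libraries were chosen after the results were seen, whereas the interactions themselves were planned.

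Responses that differed between genotypes, by an interaction test in limma, are listed here as log2 values. With ketoconazole and ncSR, 887 genes differed, among them ERG11 (−3.90), ERG6 (−3.59), ERG24 (−0.50), NCU00606 (−10.05), ci-1 (−2.51) and NCU00732 (−5.13). With amorolfine and sah2, 3692 genes differed, among them ERG24 (−2.40), ERG2 (−2.47), ERG3 at NCU06207 (−1.01) and at NCU04983 (−1.83), ERG1 (1.39), ERG11 (0.93), aod-3 (−5.84), al-1 (6.45) and vvd (5.57). With amorolfine and atrR, 1564 genes differed, among them ERG24 (−4.64), ERG2 (−3.75), ERG25 (−2.49), ERG3 at NCU06207 (−3.18) and at NCU04983 (−2.28), sah-2 (−1.36), NCU01057 (4.57) and NCU07819 (4.57). Other splits of the libraries, drawn 100 times within each treatment, gave as many genes in 3 draws for ncSR (574 with only its 4 groups in the fit), 1 for sah2 and 2 for atrR, the real one included, and the highest other draws called 2674, 1806 and 2310 genes. These draws decide nothing on an interaction, since they mix the difference between the genotypes into the values: exchanging the genotypes in 1 treatment alone called 2674, 4572 and 2637 genes. In the test of chance with the mean genotype difference removed, the real splits called 571, 3699 and 1565 genes, 1, 1 and 2 of 100 draws gave as many, the real one included, and the highest other draws called 3, 1 and 1876. With each share below 0.05, random assignment of the libraries to genotypes within a treatment is an unlikely source of these counts. The mean genotype difference was computed with the real labels, however, and exchanging the genotypes in 1 treatment alone then called 0 genes in each interaction. Some draws are thus low by construction, so the shares may be too small. If the libraries of a group came from 1 culture, the draws do not address chance differences between cultures. The atrR count was the least firm, at 897 to 2341 with 1 library left out. The draw with 1876 genes, more than the real one, exchanged wild type control replicate 2 and knockout control replicate 3 of the atrR experiment.

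For comparisons of 3 libraries with 3 there are 10 splits, too few for a share below 0.05. With only the compared libraries in the fit the real split was the 1 with the most genes in each of the 17 comparisons, and the highest other split called 0 genes except where stated. The real counts were 4791, 5417 and 5513 for terbinafine, ketoconazole and amorolfine in the inhibitor experiment, 3659, 4093 and 4001 for ketoconazole with terbinafine, ketoconazole with amorolfine and amorolfine with terbinafine, and 657, 2720 and 5454 for ncSR without inhibitor, ncSR with ketoconazole and ketoconazole in the knockout. In the sah2 experiment they were 6013, 3699, 4010 and 6310, and in the atrR experiment 4596, 8 (highest other 2), 3598 and 5466, for amorolfine in wild type, the knockout without inhibitor, the knockout with amorolfine and amorolfine in the knockout.

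Light-induced genes fell with amorolfine in wild type of the sah2 experiment, with 13 of 16 listed genes lower, 1 higher and a median of −2.86. The median lay at −2.10 or lower under all 3 scalings, which argues against the scaling of the libraries. An effect of amorolfine on wild type mycelia as such is opposed by the other experiments, where the lower of the medians was 0.32 and more of these genes were called higher than lower. In the sah2 knockout the response to amorolfine was higher than in wild type for 15 of 16 genes and lower for 0 (interaction, median 2.79). An effect of amorolfine in this experiment would thus be weaker or absent in the knockout. Among the listed genes outside the fixed lists, 6 of 6 were lower in wild type, as both more light before harvest in the other groups and such an effect of amorolfine under this experiment's conditions alone would give, so that these cannot be told apart.

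Reads of sah-2 remained in its knockout libraries, at 47.6% of wild type without inhibitor and 25.2% with amorolfine. Wild type mycelia mixed into the knockout libraries would bring every transcript in at that share, yet 25 and 6 genes of at least 100 in wild type, the fewer being 6, lay below 50% of it, which argues against such a mixture as the whole cause. The highest knockout library stood at 61.0% of the lowest wild type library or less, which argues against libraries swapped between the genotypes. Reads from a part of the locus left in place by the deletion may account for them, but read positions were not used here and this was not tested. The reads of ncSR that remained in its own knockout were not examined in this way.

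Wild type control replicate 2 of the atrR experiment lay nearer to the knockout controls (r = 0.9875, 0.9892 and 0.9901 across genes) than to its own group (0.9822 and 0.9856). Without it the count for the untreated knockout went from 218 to 1948. Knockout control replicate 3 in turn lay nearer to that wild type library (0.9901) than to its own group (0.984 and 0.9878), and without it the count was 1200. The tests below were run for the wild type library alone. Wild type control replicate 2 held atrR at 15.94 FPKM while all 6 knockout libraries list 0, which argues against a swap with an atrR knockout library. Its estimated depth, 14.1 M fragments, lay within the 13.5 to 14.2 M of the other controls, which argues against a lower depth of that library. Of 15 light-induced genes tested in this experiment 14 reached a scaled FPKM of 10 in a library, and 7 of these lay beyond both other wild type controls on the side of the knockout controls, so that a different light exposure of that culture cannot be told apart from other causes, since such a count meets neither bound. Apart from light exposure, no biological explanation was tested for this library.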

How the results depend on the processing

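Of the alternatives here, the pseudocounts of 0.1 and 5, the minimum of 5 FPKM for the lists and the named genes, only the compared groups in the fit for the named genes, the lists with the deleted gene left out and the authors' deposited comparisons were chosen after the data were seen. DESeq2 and unrounded expected counts were planned and not run, since the files hold no counts. The cause of the shifts below was not tested, except that fewer groups or libraries leave fewer residual degrees of freedom and a 2-fold minimum removes genes by construction. Among the alternative counts, 352 lay within 1.5 times the count reported. The exceptions concerned 7 results. For the ncSR knockout without inhibitor, 657 genes passed with only the compared groups in the fit and 1101 in the authors' deposited comparison, against 2011, and its interaction gave 574 with only the compared groups against 887. For the atrR knockout without inhibitor, against 218, there were 1934 with FPKM as deposited, 92 with no filter, 8 with only the compared groups and 10 to 1948 with 1 library left out. Leaving out 1 library gave 897 to 2341 for the atrR interaction. It gave 3562 to 4061 for the genes shared by the inhibitors and 2863 to 3064 for those shared by the amorolfine experiments, both within 1.5 times. A 2-fold minimum left 820 and 776 of these shared genes. With an estimated correlation camera called 0 gene lists (39 at an unadjusted p below 0.05) against 103, and the other settings called 91 to 115. A term for the replicate block gave 108 genes for the atrR knockout without inhibitor, and the numbers did not pair libraries: replicates of the same number correlated at a mean r of −0.004, −0.019 and 0.001 in the inhibitor, sah2 and atrR experiments. Among the named genes 1 alternative value reversed, ERG2 with amorolfine in the sah2 knockout at 0.36 with FPKM as deposited, against −0.34. Of the other values 21 lost and 1 gained the call. Of the alternative values for the ergosterol lists, 304 kept their side of the threshold, 9 lost the call, all with an estimated correlation, and 7 gained it, none with a reversed direction. On simulated data at 1.5-fold, 64% of changed genes below the median level were recovered and 80.6% of the others, and what depth limits was not tested, since it was not varied.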

Other observations

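The test of mating type and the light-induced genes named here were chosen after the values were seen.

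Genes induced by light, such as the photoreceptor gene vvd, the clock gene frq and the carotenoid genes al-1, al-2 and al-3, also moved with genotype. Of 16 such genes 7 were lower and 1 higher in the ncSR knockout without inhibitor, with a median of −0.56. In the atrR knockout without inhibitor, where calls rested on single libraries, 5 of 15 were lower and 0 higher, with a median of −1.09. With amorolfine 10 of 15 were lower and 0 higher in that knockout, with a median of −1.77. Apart from genotype, ketoconazole in wild type raised 8 of the 16 and lowered 1, with a median of 0.37. Of all 7806 genes tested there 5791 passed, so such calls were not particular to these genes.

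Only in the inhibitor experiment did the table hold values for the mat A genes, with matA-1 at 1.63 to 58.47 FPKM in its 18 libraries, against 0 mat A genes with a value in the 24 libraries of the other experiments. Both flanking genes, NCU01956 and NCU01962, were measured there at 20.1 FPKM or more, which is consistent with wild types of different mating type in the experiments. Since a value can be missing from a table for other reasons, and gene models differed between the tables, this remains a hypothesis.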
